A study of Drosophila melanogaster with 9 samples.

How the data were processed

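RNA was extracted from pooled heads of 3 genotypes with 3 samples each, and libraries were made from poly(A) RNA with a NEBNext Ultra kit, per the labels' protocols. The kit named does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The aligner, the counting tool, the genome build and the authors' test are not given in the sources used here.

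The authors deposited 1 table with expected counts, estimated per gene by a tool not named, and TPM for 14141 genes in the 9 samples, per the file headers. Of these, 13942 had a FlyBase ID and 199 were assembled loci without one, and 13879 of the FlyBase IDs were found in the reference name table. Gene symbols are those of the authors' table. The deposited counts were given to 2 decimals, and 92.14% of the values were whole within 1e-06, while 1616 genes had a fractional count in at least 1 sample. Fractional counts can come from reads divided among genes, so such genes, and genes with a large share of exons overlapping another gene in the reference annotation, are called uncertain. TPM as deposited by the authors summed to 1000000 in each sample. The deposited tables of the authors' comparisons give a log2 ratio of the mean TPM of 2 groups and an adjusted p-value, and hold only genes past both thresholds. A table of group means was not used, since it adds no measurement.

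Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 9925, and libraries were scaled by TMM, with factors from 0.834 to 1.128. A quasi-likelihood model with robust dispersion was fitted to all 9 samples with 3 group means, so that the groups shared 1 estimate of the spread. Each comparison used a quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and no fold threshold. The SE of a log2 fold change is its size divided by the square root of F and is approximate. Levels are TMM-normalised CPM.

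Before the data were examined, 40 gene lists were fixed, of which 39 had at least 3 tested members. Each was tested against the other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 117 tests of 3 comparisons, and again with a correlation estimated per list. The lists were also tested with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Members were counted by adjusted p over all genes and adjusted over the list alone. Of the lists called with the preset correlation, 1 in each comparison, the photoreceptor list, was also called with the estimated correlation. The samples, groups, tests, lists and the first set of alternatives were chosen before the data were examined.

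The genes named were chosen by a fixed rule. It took yki, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM, complete separation of replicates and a symbol other than a systematic one. It added up to 2 members with the largest rise and 2 with the largest fall of each list described, among those called with a mean of at least 1 CPM, or the member with the highest mean where none was called. It also took 11 anchor genes, called or not, of which CycE was not tested. Among the genes it picked, those whose calls held across the alternatives were preferred for the text, and a gene listed for one comparison may be given in another.

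The overlap of both tumor genotypes was set against 20 simulations of unchanged groups and against independent lists. In the simulations all 9 libraries were drawn from the control means, and both comparisons shared the simulated controls. Ratios of genes with 1 to 3 counts in a group have exact 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Exonic length was available for 9743 of the tested genes, 98.2%, from the reference annotation, and was used only as a property of the gene. No library pair of a group agreed within sampling noise, as the chi-square per degree of freedom ranged from 38.0 to 243.84.

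Alternatives were DESeq2 1.42.0, its size factors inside edgeR, library size alone, upper quartile scaling, no filter, a mean of at least 5 CPM, a log2 fold threshold of 1, the 6 samples compared alone, the replicate number as a block, and each sample left out in turn. Limma on log2(TPM + 1) and log2(TPM + 0.1) and removal of the length trend by offsets were added after seeing the data. Their effects are given in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

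The tests were run on simulated counts drawn from the real means and library sizes with 200 of 9925 genes changed and 30 more, a planted list, raised 2-fold. Far fewer genes were changed than the data called, so the shares recovered and false need not hold for the data. For weak tumor against control, edgeR recovered 31% of 100 genes changed 2-fold and 82% of 100 changed 4-fold, with 5.4% false among the calls. For strong tumor against control these values were 34%, 78% and 6%. DESeq2 recovered 56% and 91% with 14.7% false for weak, and 45% and 87% with 17.1% false for strong tumor against control. For the length offsets, a planted slope of -0.3 was fitted as -0.296 before and -0.005 after removal.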

Results

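RNA sequencing measured transcript levels in whole heads of Drosophila melanogaster. The 9 samples formed 3 groups of 3, and each sample pooled 50 to 80 heads. GMR-Gal4, a driver active in the eye, was present in all of them. Control heads carried the driver alone, weak tumor heads also expressed wild-type yki from a UAS transgene, and strong tumor heads expressed the yki S168A form. By their labels the controls carried no UAS transgene, and the tumor groups carried different ones. Effects of yki therefore cannot be told apart from those of transgene insertion or strain background in any comparison. The protein Yorkie, encoded by yki, is the growth-promoting coactivator restrained by the Hippo pathway, and S168A removes a serine through which that restraint acts. Summed counts ranged from 17663722 to 22867818 per sample, and 9925 genes had enough counts to be tested. Control replicate 3 stood apart from the other controls, with the yolk protein genes Yp1, Yp2 and Yp3 at 6.63, 4.17 and 4.44 times their mean level. The labels call the replicates biological without saying how heads were divided among them, so the p-values measure the spread between these 3 pools per group. Values are normalised counts per 1000000 (CPM) as mean ± SD with n = 3, fold changes are log2 values ± SE, and "rose" and "fell" refer to genes past an adjusted p of 0.05. Except where stated, each gene given as risen or fallen had its 3 libraries of one group all above the 3 of the other.

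The transgene target came first, as a check of the labels. The level of yki (FBgn0034970) was 22.3 ± 2.52 CPM in control, 198 ± 36.4 CPM in weak tumor and 173 ± 103 CPM in strong tumor heads. It rose in both tumor genotypes, by 3.15 ± 0.40, adjusted p = 0.00112 in weak and by 2.96 ± 0.40, adjusted p = 0.000522 in strong tumor heads. The counts do not separate the endogenous gene from the transgene, nor the wild-type from the S168A form. Between the tumor genotypes the difference was -0.19 ± 0.37 and did not pass the test (adjusted p = 0.732). This difference ranged from -0.75 without strong tumor replicate 2, the highest of the 3 strong tumor values, to 0.15 without strong tumor replicate 3, the lowest.

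**Figure D1:**
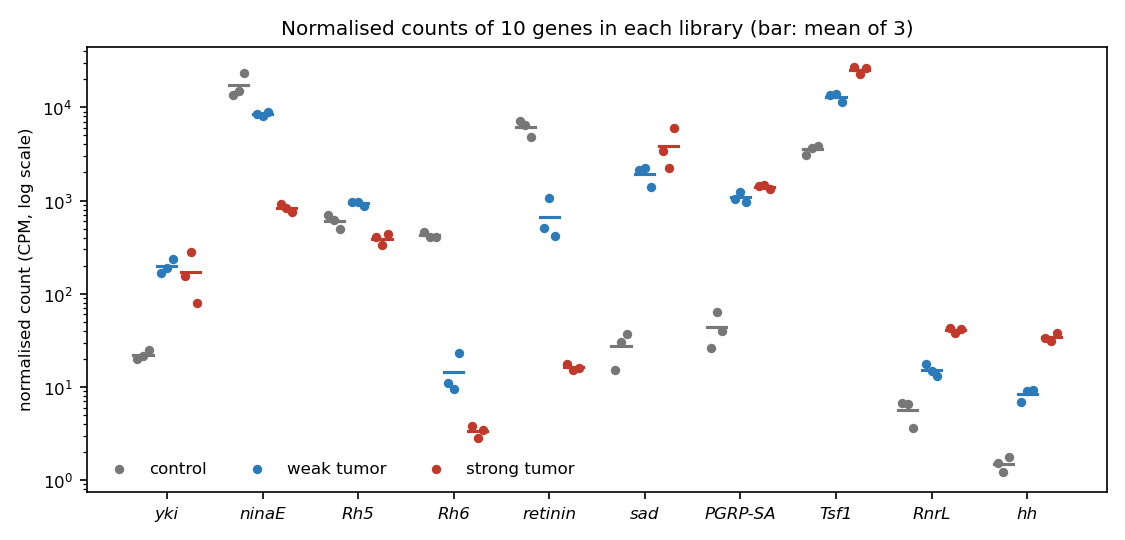
Normalised counts (CPM, log axis) of 10 genes in each of the 9 libraries, grouped by genotype, with points for libraries and bars for the mean of 3. The opsin gene Rh6 and the lens gene retinin were lower in every tumor library than in every control library, and sad, PGRP-SA and Tsf1 were higher.

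The comparison of weak tumor with control heads asked what differed in heads that expressed wild-type yki. Camera with its preset correlation called the photoreceptor list lower and the immune, JAK/STAT and ribosomal protein lists higher, and of these the photoreceptor call alone held with an estimated correlation. The R8 photoreceptor opsin Rh6 (FBgn0019940) dropped from 425 ± 31.7 to 14.5 ± 7.56 CPM, and the corneal lens gene retinin from 6124 ± 1189 to 661 ± 345 CPM. In the other direction, the ecdysone synthesis gene sad went from 27.7 ± 11.4 to 1925 ± 449.5 CPM and PGRP-SA, a secreted recognition protein of the Toll pathway, from 43.5 ± 19.3 to 1078 ± 151 CPM. In all, 982 genes rose and 522 fell, with changes of at least 2-fold in 485 and 267 of them.

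The phototransduction and photoreceptor list fell as a group in weak tumor heads: 1 of the 38 tested members rose and 25 fell, or 2 and 31 adjusted over the list alone (camera adjusted p = 5.65e-19, or 0.0254 with an estimated correlation). Its median was -1.11. Rh6 fell by the most (-4.87 ± 0.35, adjusted p = 6.61e-05). The opsin gene of the outer photoreceptors, ninaE, changed by -1.01 ± 0.20, adjusted p = 0.00925, from 17150 ± 5188 to 8504 ± 421 CPM. The only member that rose was Rh5, another R8 opsin (0.64 ± 0.17, adjusted p = 0.0335). That rise was called in 8 of 20 alternatives, over which its adjusted p ranged from 0.00961 to 0.125. It was not called without control replicate 2 (0.0871), control replicate 3 (0.0523), strong tumor replicate 1 (0.0582), or weak tumor replicate 1 (0.11), 2 (0.125) or 3 (0.0594). Among lens and accessory eye cell genes, 3 of the 12 tested members rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.47, or 0.91 with an estimated correlation). It had a median of 0.30 and a mean of -0.06. The lens genes retinin (-3.21 ± 0.34, adjusted p = 0.000403) and Cpr72Ec (-2.59 ± 0.16, adjusted p = 4.66e-05) fell, whereas Crys, which encodes a crystallin of the corneal lens, rose (2.45 ± 0.45, adjusted p = 0.00683). The R8 gene boss, the ligand of Sevenless, fell (-1.49 ± 0.16, adjusted p = 0.000404), and the eye transcription factor gene lz rose (1.20 ± 0.19, adjusted p = 0.00345). Of the pigmentation genes, w, a pigment transporter gene that is also a common transgene marker, rose to 329.7 ± 21.0 from 55.1 ± 8.77 CPM, and pr fell (-2.30 ± 0.29, adjusted p = 0.00113).

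Lists of signalling and immune genes were called higher in weak tumor heads. For the JAK/STAT pathway, 11 of the 15 tested members rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.61e-06, or 0.253 with an estimated correlation). The ligand gene upd1 rose (4.14 ± 0.61, adjusted p = 0.0021) at low counts, as did the stress-induced secreted factor gene TotM (5.15 ± 0.84, adjusted p = 0.0041). The ligand gene upd3 had 1 count over the 3 control libraries and 26 over the weak tumor libraries, a ratio of 26.7 with an exact 95% interval of 4.39 to 1100 for counting error. In the gene tests of 18 alternatives upd3 was called in 7, with an adjusted p from 0.0113 to 0.494. Antimicrobial peptide and Toll/Imd genes gave a similar picture, as 15 of the 46 tested members rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 3.55e-10, or 0.666 with an estimated correlation). Examples were PGRP-SA (4.63 ± 0.32, adjusted p = 6.61e-05) and CecA2 (7.25 ± 1.25, adjusted p = 0.00499). Outside the list, Diedel, a secreted immune regulator gene, rose (7.58 ± 0.80, adjusted p = 0.000397). In the JNK and invasion list 7 of the 21 tested members rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.00193, or 0.746 with an estimated correlation). There scaf rose (2.58 ± 0.20, adjusted p = 0.000102), as did Ets21C (2.95 ± 0.38, adjusted p = 0.00119), which is uncertain because its counts were fractional and 28.3% of its exons overlap another gene. For Hippo pathway components, 6 of the 23 tested members rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.0116, or 0.746 with an estimated correlation). The cadherin gene ds was at 2.04 ± 0.25, adjusted p = 0.00092 and jub at 0.91 ± 0.16, adjusted p = 0.00549. The Wnt, Hedgehog and Dpp list was also called higher, with a minority of members past the test: 5 of the 25 tested members rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0228, or 0.746 with an estimated correlation). The call ended without weak tumor replicate 3 (0.105), and over 20 settings the adjusted p ranged from 0.000273 to 0.105. Without that library the list median went from 0.30 to -0.01. The Hedgehog ligand gene hh (2.47 ± 0.20, adjusted p = 0.000126) and its receptor gene ptc (2.79 ± 0.42, adjusted p = 0.00255) were among the risers.

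Growth-related lists were also called higher in weak tumor heads. For cytosolic ribosomal proteins, 32 of the 86 tested members rose and 0 fell, or 53 and 1 adjusted over the list alone (camera adjusted p = 2.36e-07, or 0.854 with an estimated correlation), with a median of 0.48. For cell cycle and DNA replication genes, 11 of the 55 tested members rose and 0 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.0149, or 0.746 with an estimated correlation). That call ended without control replicate 3 (0.0985), and over 20 settings the adjusted p ranged from 0.000942 to 0.0985. The origin recognition gene Orc2 rose at low counts (2.04 ± 0.39, adjusted p = 0.00825). The cell death inhibitor gene Diap1 rose from 444 ± 52.5 to 807 ± 38.2 CPM (0.86 ± 0.14, adjusted p = 0.00392). Of the other Yorkie targets, fj at -0.46 ± 0.47, adjusted p = 0.556 and ex at 0.91 ± 0.67, adjusted p = 0.398 did not pass the test, ex being below 1 CPM and with fractional counts, and CycE had too few counts to be tested. Over the 16 tested Yorkie target genes, 4 rose and 0 fell, or 4 and 0 adjusted over the list alone, and the list was not called (camera adjusted p = 0.219).

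The muscle and oxidative phosphorylation lists were called lower in weak tumor heads with a minority of members past the test, and members of the sensory list moved both ways. In the muscle list 0 of the 22 tested members rose and 7 fell, or 0 and 12 adjusted over the list alone (camera adjusted p = 4.11e-06, or 0.746 with an estimated correlation). The troponin C gene TpnC4 was at -4.48 ± 0.89, adjusted p = 0.00974 on low counts. For mitochondrial oxidative phosphorylation, 0 of the 66 tested members rose and 12 fell, or 0 and 14 adjusted over the list alone (camera adjusted p = 2.11e-07, or 0.854 with an estimated correlation). For odorant-binding proteins and chemoreceptors, 5 of the 75 tested members rose and 6 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.0127, or 0.854 with an estimated correlation). The call ended without control replicate 2 (0.165) or 3 (0.0985), with library size alone and in the limma fits of TPM, and over 20 settings the adjusted p ranged from 6.82e-08 to 0.165. The member Obp19c went the other way (2.27 ± 0.31, adjusted p = 0.00158). In the neuronal list 1 of the 25 tested members rose and 4 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.0246, or 0.854 with an estimated correlation), a call that held in 11 of 20 settings. It ended without control replicate 1 (0.0781) or 3 (0.108) and without weak tumor replicate 1 (0.086) or 2 (0.151), and over 20 settings the adjusted p ranged from 0.00286 to 0.151. The synaptic vesicle gene nSyb fell (-1.23 ± 0.22, adjusted p = 0.00602) and ple, the tyrosine hydroxylase gene, rose (2.27 ± 0.41, adjusted p = 0.00659). For heat shock proteins, 2 of the 15 tested members rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0369, or 0.854 with an estimated correlation), and this call ended with DESeq2, at a mean of at least 5 CPM, and without control replicate 2 (0.109) or 3 (0.253) or weak tumor replicate 1 (0.115); over 20 settings the adjusted p ranged from 0.000596 to 0.253. Other genes with large changes were Tig, an extracellular matrix gene (3.05 ± 0.22, adjusted p = 6.62e-05), the iron carrier gene Tsf1 (1.86 ± 0.15, adjusted p = 0.000102), the cytochrome P450 gene Cyp4p2 (-5.75 ± 0.56, adjusted p = 0.000278) and the glial transporter gene Gat (-0.92 ± 0.18, adjusted p = 0.00904). The glial marker repo was at -0.19 ± 0.19, adjusted p = 0.548, and Mmp1 (0.54 ± 0.28, adjusted p = 0.223), Ilp8 (-1.10 ± 0.39, adjusted p = 0.0871), elav (0.45 ± 0.51, adjusted p = 0.601) and ImpL2 (0.97 ± 0.34, adjusted p = 0.0878), 61.9% of whose exons overlap another gene, did not pass the test.

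The weak tumor calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3042 genes were below an unadjusted p of 0.05. Complete separation of the 3 libraries from the other 3 held for 34.8% of genes, against 10% by chance. Of the genes called, 65.3% were higher with TMM scaling, against 49.2% with upper quartile, 44.0% with library size alone and 38.3% in limma on log2(TPM + 1), so directions are relative to the TMM scale. Library size alone moved the median log2 fold change by -0.167. Leaving out a library moved the 982 higher genes to 573 (weak tumor replicate 1) or 566 (weak tumor replicate 2). The 522 lower genes became 176, 254 and 294 without weak tumor replicates 1, 2 and 3, and 273 and 875 without control replicates 2 and 3.

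**Figure D2:**
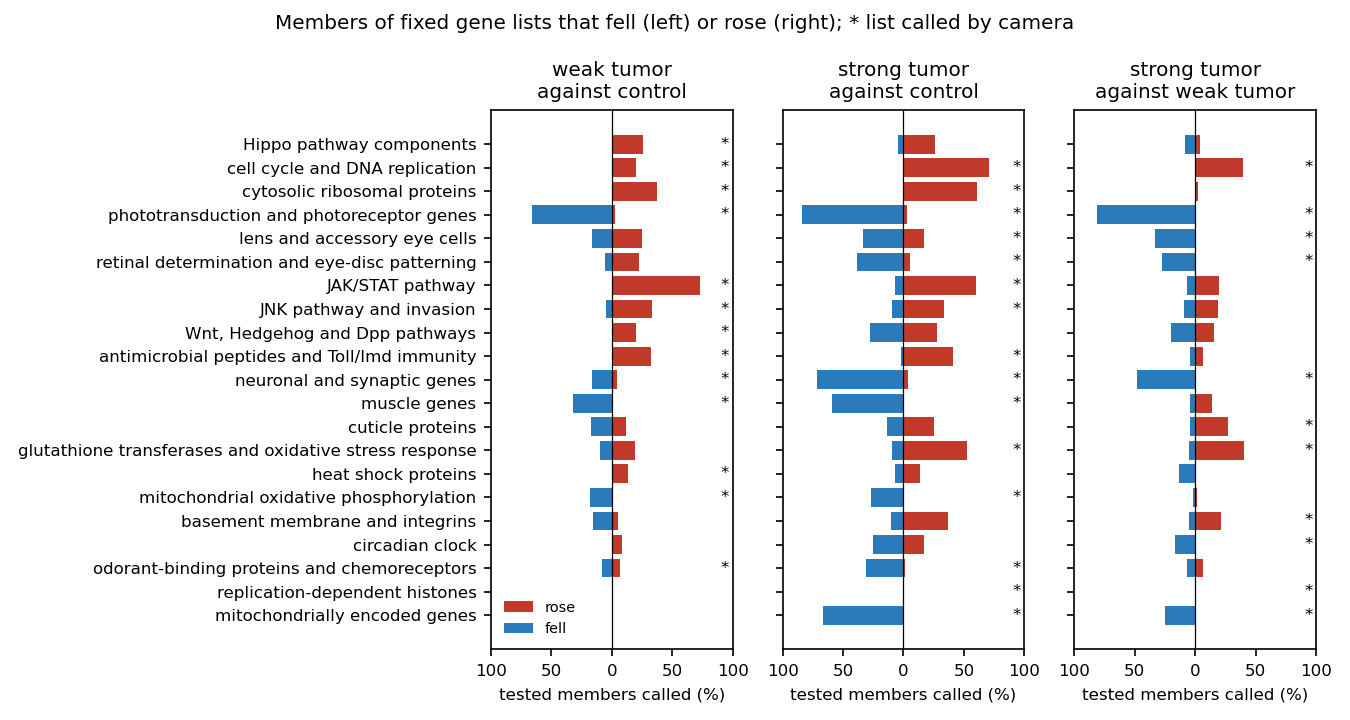
Share of tested members (percent) of the gene lists called in at least 1 comparison that fell (left, blue) or rose (right, red), in 3 panels for the 3 comparisons, with an asterisk where camera called the list with its preset correlation. Photoreceptor genes fell in all 3 panels, with 25, 32 and 31 of 38 members called, and the share of cell cycle genes that rose was larger in strong than in weak tumor heads (39 and 11 of 55).

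The comparison of strong tumor with control heads asked what differed in heads that expressed the S168A form. The photoreceptor and neuronal lists were called lower and the cell cycle, glutathione transferase and immune lists higher, and of these the photoreceptor call alone held with an estimated correlation. The opsin gene ninaE went from 17150 ± 5188 to 835 ± 76.5 CPM and retinin from 6124 ± 1189 to 16.3 ± 1.11 CPM. The ribonucleotide reductase gene RnrL went from 5.64 ± 1.76 to 41.0 ± 2.44 CPM and the glutathione transferase gene GstD9 from 35.2 ± 10.2 to 645 ± 118 CPM. In all, 2136 genes rose and 1953 fell, with changes of at least 2-fold in 971 and 1304.

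The photoreceptor list fell in strong tumor heads as well: 1 of the 38 tested members rose and 32 fell, or 2 and 33 adjusted over the list alone (camera adjusted p = 6.84e-48, or 0.00187 with an estimated correlation), with a median of -3.07. The largest falls were those of Rh6 (-6.98 ± 0.39, adjusted p = 4.00e-06) and of the retinal dehydrogenase gene Pdh (-6.36 ± 0.43, adjusted p = 9.81e-06), which is uncertain because 43.3% of its exons overlap another gene. The outer photoreceptor opsin gene ninaE fell as well (-4.36 ± 0.23, adjusted p = 3.52e-06). In the lens and accessory eye cell list 2 of the 12 tested members rose and 4 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.0111, or 0.746 with an estimated correlation; not called in the limma fits of TPM). Its lens genes retinin (-8.55 ± 0.44, adjusted p = 3.52e-06) and Cpr72Ec (-4.38 ± 0.18, adjusted p = 1.37e-06) fell and lz rose (1.64 ± 0.19, adjusted p = 0.000237). For retinal determination and eye-disc patterning, 1 of the 18 tested members rose and 7 fell, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.0337, or 0.854 with an estimated correlation). That call held in 12 of 20 settings and ended, among others, without control replicate 3 (0.154), strong tumor replicate 2 (0.0593) or 3 (0.0669), and over 20 settings the adjusted p ranged from 0.017 to 0.157. The member boss fell (-3.24 ± 0.17, adjusted p = 3.52e-06) and so, a gene of the core eye network, rose (0.81 ± 0.12, adjusted p = 0.000842). Pigmentation genes moved both ways, with w (3.69 ± 0.21, adjusted p = 4.21e-06) and cd (2.42 ± 0.23, adjusted p = 5.89e-05) higher and the transporter gene st (-2.94 ± 0.41, adjusted p = 0.000645) lower.

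The cell cycle and ribosomal protein lists were called higher in strong tumor heads with the preset correlation. For cell cycle and DNA replication, 39 of the 55 tested members rose and 0 fell, or 39 and 0 adjusted over the list alone (camera adjusted p = 7.91e-10, or 0.207 with an estimated correlation), with a median of 1.31. Members with large rises were Incenp, of the chromosomal passenger complex (2.90 ± 0.41, adjusted p = 0.000698), and RnrL (2.86 ± 0.24, adjusted p = 3.60e-05). For cytosolic ribosomal proteins, 52 of the 86 tested members rose and 0 fell, or 57 and 0 adjusted over the list alone (camera adjusted p = 7.22e-05, or 0.854 with an estimated correlation), and the call ended when the trend with transcript length was removed (0.0512); over 20 settings the adjusted p ranged from 4.61e-07 to 0.0512. Among ribosome biogenesis genes, 8 of the 25 tested members rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.232, or 0.91 with an estimated correlation). The member eIF6 was at 1.11 ± 0.14, adjusted p = 0.000353. For replication-dependent histones no member of 11 was called, at 0 risen and 0 fallen adjusted over the list alone, yet the list was called (camera adjusted p = 0.0246, or 0.854 with an estimated correlation), though not with DESeq2. Of 111 such genes only these 11 had enough counts to be tested. Their estimated correlation was 0.874, so they hold far fewer than 11 independent values. Yorkie target genes gave 6 risen and 1 fallen of 16, or 7 and 1 adjusted over the list alone, without a call (camera adjusted p = 0.232, or 0.854 with an estimated correlation). Among them Diap1 reached 1004 ± 95.9 CPM (1.18 ± 0.14, adjusted p = 0.000278), while fj (-0.32 ± 0.47, adjusted p = 0.608) and ex (0.25 ± 0.69, adjusted p = 0.791) did not pass the test.

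Lists of signalling, immune and detoxification genes were also called higher in strong tumor heads. In the JAK/STAT list 9 of the 15 tested members rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.000185, or 0.424 with an estimated correlation). The ligand gene upd2 was at 6.64 ± 0.72, adjusted p = 0.000151 and TotM at 6.20 ± 0.88, adjusted p = 0.000765. The member that fell was Stat92E, called in 18 of 20 alternatives. It had 14.46, 16.06 and 9.57 CPM in the strong tumor libraries against 22.45, 23.25 and 54.26 CPM in the controls. The ligand gene upd3 had 121 counts over the strong tumor libraries against 1 over the controls, a ratio of 137 with an exact 95% interval of 24.1 to 5460 for counting error. For antimicrobial peptides and Toll/Imd immunity, 19 of the 46 tested members rose and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 5.45e-06, or 0.746 with an estimated correlation). The recognition protein gene PGRP-SA was at 5.02 ± 0.33, adjusted p = 7.21e-06 and the defensin gene Def at 3.38 ± 0.68, adjusted p = 0.00472. In the JNK list 7 of the 21 tested members rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00321, or 0.746 with an estimated correlation), where scaf rose (2.77 ± 0.20, adjusted p = 1.56e-05) and bsk, which encodes the JNK kinase itself, fell (-1.63 ± 0.26, adjusted p = 0.00135). For glutathione transferases and oxidative stress genes, 22 of the 42 tested members rose and 4 fell, or 22 and 5 adjusted over the list alone (camera adjusted p = 4.94e-06, or 0.317 with an estimated correlation). Its member GstD9 was at 4.19 ± 0.26, adjusted p = 5.45e-06 and GstD5 at 5.93 ± 0.45, adjusted p = 1.74e-05. Hippo pathway components were not called in strong tumor heads, where 6 of the 23 tested members rose and 1 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.34, or 0.883 with an estimated correlation). With the length trend removed, a setting added after seeing the data, the Hippo list was called higher there (camera adjusted p = 0.0412). Over 20 settings its adjusted p ranged from 0.0412 to 0.458. After subtraction of genes of like length its median went from 0.13 to 0.49 ± 0.19, beside 0.44 ± 0.14 in weak tumor heads. Wnt, Hedgehog and Dpp genes were not called either, where 7 of the 25 tested members rose and 7 fell, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.477, or 0.91 with an estimated correlation), with a median of -0.62 and a mean of 0.04. At a mean of at least 5 CPM this list was called higher (camera adjusted p = 0.0128), with its median at 0.45. Over 20 settings its adjusted p ranged from 0.0128 to 0.633. Single ligand genes, hh (4.50 ± 0.22, adjusted p = 2.99e-06), Wnt6 (3.21 ± 0.20, adjusted p = 6.83e-06) and Pvf1 (2.61 ± 0.17, adjusted p = 7.02e-06) rose, and the relaxin-like hormone gene Ilp8 rose at low counts (1.47 ± 0.36, adjusted p = 0.011). ImpL2, a secreted antagonist of insulin, rose (1.86 ± 0.35, adjusted p = 0.0029) with the uncertainty of its exon overlap. Further rises were those of the laminin gene LanB2 (2.07 ± 0.21, adjusted p = 0.000114), the glucose transporter gene Glut1 (1.96 ± 0.28, adjusted p = 0.000644) and the lactate dehydrogenase gene Ldh (1.80 ± 0.31, adjusted p = 0.00181). Mmp1, a matrix metalloproteinase gene, stood at 0.76 ± 0.28, adjusted p = 0.0515.

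The neuronal, muscle and mitochondrial lists were called lower in strong tumor heads with the preset correlation. For neuronal and synaptic genes, 1 of the 25 tested members rose and 18 fell, or 1 and 19 adjusted over the list alone (camera adjusted p = 8.90e-06, or 0.744 with an estimated correlation). The vesicle gene nSyb was at -2.79 ± 0.23, adjusted p = 3.22e-05 and Snap25 at -2.91 ± 0.59, adjusted p = 0.0046. The same libraries showed a trend with transcript length: the median log2 fold change over all genes was 0.13 in the 10% with the shortest exonic length and -0.70 in the 10% with the longest (median 7557 bases). After subtraction of the median of genes of like length, the neuronal median went from -1.71 to -1.23 ± 0.27 and the photoreceptor median from -3.07 to -2.54 ± 0.39. In the muscle list 0 of the 22 tested members rose and 13 fell, or 0 and 13 adjusted over the list alone (camera adjusted p = 0.00204, or 0.854 with an estimated correlation). The troponin I gene wupA was at -1.35 ± 0.24, adjusted p = 0.00259. For mitochondrial oxidative phosphorylation, 0 of the 66 tested members rose and 18 fell, or 0 and 15 adjusted over the list alone (camera adjusted p = 0.00317, or 0.91 with an estimated correlation). The call ended without control replicate 1 (0.076), and over 20 settings the adjusted p ranged from 6.74e-08 to 0.076. The complex I gene ND-B14 fell (-0.95 ± 0.13, adjusted p = 0.000687). Among mitochondrially encoded genes, 0 of the 12 tested members rose and 8 fell, or 0 and 10 adjusted over the list alone (camera adjusted p = 0.00702, or 0.777 with an estimated correlation). The gene mt:ATPase6 was at -1.21 ± 0.30, adjusted p = 0.0122. For odorant-binding proteins and chemoreceptors, 1 of the 75 tested members rose and 23 fell, or 1 and 20 adjusted over the list alone (camera adjusted p = 0.00332, or 0.854 with an estimated correlation). Other genes were the septate junction scaffold gene dlg1 (-2.96 ± 0.24, adjusted p = 2.77e-05) and the neuropeptide genes sNPF (-2.20 ± 0.51, adjusted p = 0.00825) and Pdf (-1.45 ± 0.15, adjusted p = 0.000109), which fell. The glial transporter gene Gat fell from 165 ± 30.6 to 58.5 ± 7.39 CPM (adjusted p = 0.000287). The blood-brain barrier gene moody rose (1.88 ± 0.33, adjusted p = 0.00216) and repo was at -0.06 ± 0.19, adjusted p = 0.824.

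The strong tumor calls came from the same edgeR test, with 5064 genes below an unadjusted p of 0.05 and complete separation of the libraries for 52.2% of genes, against 10% by chance. Of the genes called, 52.2% were higher, against 37.7% with upper quartile scaling, 27.6% with library size alone and 27.4% in limma on log2(TPM + 1), and library size alone moved the median log2 fold change by -0.319. The 1953 lower genes became 1279 and 1285 without strong tumor replicates 1 and 3.

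The direct comparison of the tumor genotypes asked how heads with the S168A form differed from heads with wild-type yki. In strong tumor heads the photoreceptor, lens and neuronal lists were called lower and the cell cycle and glutathione transferase lists higher, and of these the photoreceptor call alone held with an estimated correlation. The opsin gene ninaE stood at 835 ± 76.5 against 8504 ± 421 CPM, and Arc1, which encodes a capsid-like RNA carrier, at 7782 ± 1177 against 364 ± 125 CPM. Cyclin B (CycB) had 6.80 ± 2.55 against 0.464 ± 0.257 CPM and Cyp4p2 37.9 ± 6.20 against 0.169 ± 0.172 CPM. Control replicates 1, 2 and 3 had 3.93, 1.74 and 0.69 CPM of CycB, so part of its gap may lie in a low weak tumor level. In all, 917 genes were higher and 892 lower in strong tumor heads, with at least 2-fold differences in 404 and 585.

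Among the eye lists, 0 of the 38 tested members rose and 31 fell, or 2 and 32 adjusted over the list alone for photoreceptor genes (camera adjusted p = 7.49e-43, or 0.00187 with an estimated correlation). The opsin gene ninaE was at -3.35 ± 0.22, adjusted p = 7.61e-05. For lens and accessory eye cells, 0 of the 12 tested members rose and 4 fell, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.000175, or 0.536 with an estimated correlation; not called in limma on log2(TPM + 1)). The lens gene retinin was at -5.34 ± 0.38, adjusted p = 7.75e-05 and Crys at -2.33 ± 0.45, adjusted p = 0.00996. For retinal determination genes, 0 of the 18 tested members rose and 5 fell, or 0 and 7 adjusted over the list alone (camera adjusted p = 0.000584, or 0.746 with an estimated correlation). The gene tsh was at -2.04 ± 0.35, adjusted p = 0.00623. The cell cycle and DNA replication list was called higher in strong tumor heads, where 22 of the 55 tested members rose and 0 fell, or 33 and 0 adjusted over the list alone (camera adjusted p = 3.10e-10, or 0.189 with an estimated correlation). Its gene CycB was at 3.83 ± 0.68, adjusted p = 0.0074. The glutathione transferase and oxidative stress list was also higher, in that 17 of the 42 tested members rose and 2 fell, or 24 and 2 adjusted over the list alone (camera adjusted p = 7.54e-10, or 0.189 with an estimated correlation). In that list GstD5 was at 6.76 ± 0.47, adjusted p = 7.75e-05 and GstE5 at 4.17 ± 0.28, adjusted p = 7.75e-05. For basement membrane and integrin genes, 4 of the 19 tested members rose and 1 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0451, or 0.854 with an estimated correlation), a call that held in 8 of 20 settings. It ended without control replicate 2 (0.0584) or 3 (0.0961), weak tumor replicate 1 (0.0875) or 3 (0.062) and strong tumor replicate 1 (0.0997) or 2 (0.171), and over 20 settings the adjusted p ranged from 4.58e-05 to 0.171. Its members LanB2 (2.34 ± 0.22, adjusted p = 0.000292) and Col4a1 (0.93 ± 0.17, adjusted p = 0.0076) rose. The secreted factor genes upd2 (3.88 ± 0.59, adjusted p = 0.00377), Ilp8 (2.57 ± 0.39, adjusted p = 0.00367), hh (2.02 ± 0.19, adjusted p = 0.000312) and Wnt6 (1.18 ± 0.19, adjusted p = 0.00488) were higher too, as was Arc1 (4.42 ± 0.30, adjusted p = 7.75e-05).

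For neuronal and synaptic genes, 0 of the 25 tested members rose and 12 fell, or 0 and 13 adjusted over the list alone (camera adjusted p = 3.95e-05, or 0.746 with an estimated correlation). The length trend was present here as well, with medians of 0.20 in the shortest and -0.70 in the longest 10% of genes. Subtraction took the neuronal median from -1.28 to -0.52 ± 0.15. In the circadian clock list 0 of the 12 tested members rose and 2 fell, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.0286, or 0.854 with an estimated correlation), and the call ended without weak tumor replicate 1 (0.0733), at a mean of at least 5 CPM, in the fit of the 6 samples alone and with the length trend removed, and over 20 settings the adjusted p ranged from 0.00493 to 0.156. The neuropeptide gene Pdf fell (-1.10 ± 0.15, adjusted p = 0.00242). Among mitochondrially encoded genes, 0 of the 12 tested members rose and 3 fell, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.0228, or 0.854 with an estimated correlation). That call ended without weak tumor replicate 2 (0.124) or strong tumor replicate 2 (0.122), and over 20 settings the adjusted p ranged from 0.00113 to 0.124. The member mt:Cyt-b fell (-1.02 ± 0.13, adjusted p = 0.00193). The histone list was called with 0 of 11 members called and 0 adjusted over the list alone (camera adjusted p = 0.0176, or 0.854 with an estimated correlation, which was 0.906). For cuticle proteins, 14 of the 51 tested members rose and 2 fell, or 17 and 2 adjusted over the list alone (camera adjusted p = 0.000134, or 0.854 with an estimated correlation). Summed cuticle protein counts were 1323 to 1573 CPM in the weak tumor libraries, 2215 to 3318 CPM in the strong tumor libraries, 3311 and 3017 CPM in control replicates 1 and 2, and 1785 CPM in control replicate 3. The P450 gene Cyp4p2 rose (7.79 ± 0.57, adjusted p = 8.28e-05), and Obp19c (-4.10 ± 0.34, adjusted p = 0.00019) and Cyp304a1 (-4.09 ± 0.81, adjusted p = 0.0118) fell.

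The direct calls also came from the edgeR test, with 3596 genes below an unadjusted p of 0.05 and 47.2% of genes separated completely, against 10% by chance. Of those called, 50.7% were higher, against 33.5% with library size alone and 39.4% in limma on log2(TPM + 1). The 917 higher genes became 435, 476 and 327 without weak tumor replicates 1, 2 and 3, 446 and 505 without strong tumor replicates 1 and 3, and 1414 without control replicate 3. The 892 lower genes became 454, 591 and 286 without weak tumor replicates 1, 2 and 3, 337, 452 and 405 without strong tumor replicates 1, 2 and 3, and 1376 without control replicate 3.

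Both tumor genotypes shared much of their change from control. Against control, 799 genes rose in both and 340 fell in both, 1139 in all, where independent lists of these lengths would share 211.3 and 102.7. Genes that rose in both included sad, PGRP-SA, Diedel, Tig and w, and genes that fell in both included Rh6, retinin, ninaE, boss and nSyb. For 314 genes, all 3 comparisons were called in the graded order control, weak, strong or its reverse. Across genes, the covariance of both sets of log2 fold changes was 0.687 and the correlation 0.624, beside 0.086 and 0.49 in 20 simulations of unchanged groups against the same controls, in which 0 genes were called in both; genes are not independent replicates. The 3 control libraries could not be split into groups of at least 2, so part of the excess may come from the shared controls. The 1139 shared genes became 623 and 634 without weak tumor replicates 1 and 2.

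**Figure D3:**
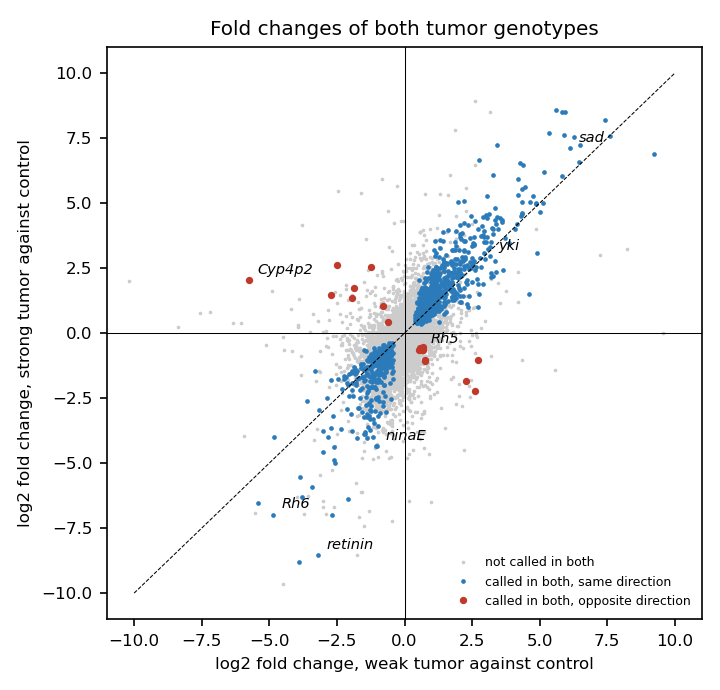
Log2 fold change of each of 9925 genes in weak (x axis) and strong tumor heads (y axis), both against control, with genes called in both coloured by whether the directions matched and a dashed line of equal change. The 1139 genes called in the same direction lie where both changes were rises or both were falls, and 19 genes were called in opposite directions. Of the genes called in strong tumor heads, 92.4% had a smaller absolute log2 fold change in weak tumor heads. Choosing genes by their strong tumor call favours this, and no chance share was computed, so the share does not measure a graded effect.

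The authors' deposited tables list genes with an adjusted p under 0.05 and at least a 2-fold ratio. For weak tumor against control, the authors' deposited table held 860 genes (387 higher, 473 lower), and 696 of the 841 tested here, 82.8%, were called in the same direction. For strong tumor against control, the authors' deposited table held 2479 genes (662 higher, 1817 lower), of which 2283 of 2413 tested, 94.6%, were called in the same direction. For the tumor genotypes, the authors' deposited table held 1412 genes (402 higher, 1010 lower), and 976 of 1372 tested, 71.1%, matched. No tested gene of these tables had the opposite sign, a count of 0 in each comparison.

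**Figure D4:**
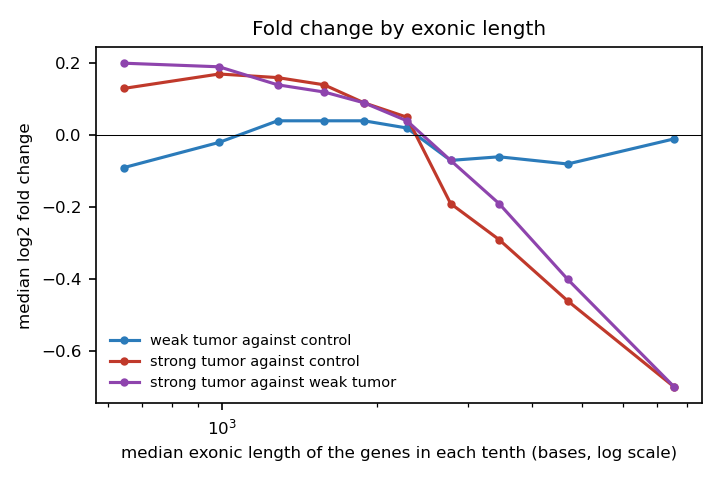
Median log2 fold change of genes in bins of 10% by exonic length (x axis, bases, log scale) for the 3 comparisons. Medians fell to -0.70 in the longest 10% in both comparisons of strong tumor heads and stayed between -0.09 and 0.04 for weak tumor against control.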

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

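The tests of an equal loss of all opsins and of library scaling, and the values of the markers in weak tumor heads, were chosen only after the results were seen, and the other tests in this part were written before their results.

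In 19 genes the change from control had opposite signs in weak and strong tumor heads, both past the threshold. The design cannot tell effects of the yki forms from those of the transgene lines here. All 19 also passed the edgeR test between the tumor genotypes, which this choice of genes favours, since that difference is the sum of both changes. Among them Obp19c was 2.27 ± 0.31 in weak and -1.83 ± 0.33 in strong tumor heads, and Rh5 was 0.64 ± 0.17 and -0.62 ± 0.17. In the other direction, Cyp4p2 was -5.75 ± 0.56 and 2.03 ± 0.39, GstE5 -2.71 ± 0.26 and 1.46 ± 0.24, and Cyp6a2, chosen after its values were seen, -1.93 ± 0.20 and 1.36 ± 0.20. The rise of Rh5 in weak tumor heads was not called in 12 of 20 alternatives; without control replicate 2 or 3, strong tumor replicate 1, or weak tumor replicate 1, 2 or 3 its adjusted p was 0.0871, 0.0523, 0.0582, 0.11, 0.125 and 0.0594.

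The photoreceptor list fell in both tumor genotypes, with medians of -1.11 in weak and -3.07 in strong tumor heads. A trend with transcript length would have brought the strong tumor median near 0 once genes of like length were subtracted, but it stayed at -2.54 ± 0.39. The scaling of the libraries, which moves every gene alike, is argued against by the list's median of -3.01 ± 0.37 relative to the other tested genes. An equal loss of all photoreceptor transcripts, as from a smaller share of retina in the head, would leave the 5 opsins of the compound eye with 1 common fold change, but they scattered with a chi-square per degree of freedom of 53.9 in weak and 96.3 in strong tumor heads. The contrast of Rh6 and Rh5, seen before this test was chosen, already makes the opsins scatter. The test therefore cannot exclude an equal loss of most other photoreceptor transcripts, nor a smaller share of retina as a main cause. What stays open is how far the loss of cells and lower transcription per cell, both possible effects of the yki genotype, each contribute, since heads were not separated into cell types.

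The neuronal and synaptic list fell in strong tumor heads, together with long transcripts of all kinds, by a median of -0.70 in the longest 10% of genes. As the whole cause, the length trend is argued against by a median of -1.23 ± 0.27 after subtraction, from -1.71 before, although the median against weak tumor heads moved further, from -1.28 to -0.52 ± 0.15, so that the trend may carry part of it. The difference between the longest and the shortest 10% of genes was -0.36, -0.35 and -0.79 in strong tumor libraries 1, 2 and 3. It was 0.14, -0.14 and 0.65 in control libraries 1, 2 and 3 and 0.11, 0.03 and 0.64 in weak tumor libraries 1, 2 and 3. It varied within genotypes, yet every strong tumor library lay below every other library. Whether RNA quality or the genotype sets this trend stays open, because the labels give no measure of RNA quality. Loss of neurons or of their transcripts with the S168A form also stays open, untested.

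Control replicate 3 differed from the other 2 controls by a chi-square per degree of freedom of 243.84 and 187.84, against 44.1 between those, and its yolk protein genes were 4.17 to 6.63 times higher. A larger share of female heads needed a fall of male-biased genes, but 4 of them had a median log2 difference of 0.34 ± 0.56. With so few genes and this spread a fall is not excluded, so a larger female share stays open. Of 2 other female-biased genes, fit was at 1.81 and Obp99a at -0.04. Heads taken longer after emergence remain a candidate explanation: 8 markers of newly emerged flies had a median of -1.41 ± 0.57, and 43 of 51 cuticle protein genes were lower, with a median of -1.04. The weak tumor libraries had high summed yolk protein counts (26960 to 37600 CPM, against 6706 and 7013 CPM in control replicates 1 and 2) and low summed cuticle protein counts (1323 to 1573 against 3311 and 3017 CPM). Against the same 2 controls, 6 of the 8 markers of newly emerged flies were lower (median -0.60 ± 0.51), with Lsp1beta (1.17) and ple (2.12) higher. Of the female-biased genes, fit was at 3.1 and Obp99a at -1.0 there. The male-biased genes Cyp4d21, sxe2, Obp99b and to were at -0.01, -0.3, -0.89 and -0.44. Whether the weak tumor libraries share the reason with control replicate 3 stays open, as neither age nor a larger female share can be separated from genotype there. The labels give neither the age nor the sex of the flies, so neither explanation could be set against them.

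The 6 libraries of each comparison can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In edgeR fits of those 6 libraries, the real division called 1172 genes for weak tumor against control, 3232 for strong tumor against control and 2510 between the tumor genotypes, 1 of the 10 divisions each time, and the highest of the others called 0. For the gene lists, the real divisions called 13, 15 and 11 lists, and 6, 4 and 7 of the 10 divisions called as many or more, with up to 20, 21 and 16 lists in another division.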

How the results depend on the processing

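The limma fits of TPM and the removal of the length trend were chosen after seeing the data, and the other alternatives before. No gene called in the main test was called in the opposite direction in any setting. Counts that moved by more than 1.5 times and covariances that moved by more than the jackknife error were as follows. DESeq2, with 14.7% false calls in simulated counts against 5.4% for edgeR, called 893 genes lower in weak tumor heads, with a covariance of both sets of fold changes of 0.930, and no filter gave a covariance of 1.032. With library size alone, 875 genes were lower in weak, 1245 higher in strong and 3263 lower in strong tumor heads. A log2 fold threshold of 1 left 485 higher and 267 lower (weak), 971 higher (strong), 404 higher and 585 lower (strong against weak) and 512 shared genes; by construction it removes small changes. Limma on log2(TPM + 1) gave 1083 lower (weak), 1202 higher and 3184 lower (strong), 573 higher (strong against weak) and a covariance of 0.376, and on log2(TPM + 0.1) 997, 1199, 3301 and 594. The shared genes fell to 507 at an adjusted p of 0.01. The gene lists called fell from 13, 15 and 11 to 1 in each comparison with camera's estimated correlation, the photoreceptor list, and fry, which does not compare a list with other genes, called 10, 15 and 10. Apart from these list tests, 24 of 39 list calls held in all 20 settings, 1 more, the histone list between the tumor genotypes, in all 19 that could test it, and 0 turned direction with a call. Of 78 list results without a call, 19 gained one in at least 1 setting. Except where a setting tests or counts fewer genes, the cause was not tested.

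With the replicate number as a block, 649 genes were higher and 277 lower (weak), 538 higher and 515 lower (strong against weak), and 725 were shared. The numbers do not pair the samples: correlations of same-numbered deviations ranged from -0.37 to 0.36, and 2 of 9 samples correlated best with their own number.

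Leaving out each library in turn gave 566 to 1160 higher and 176 to 875 lower (weak), 1279 to 1875 lower (strong), 327 to 1414 higher and 286 to 1376 lower (strong against weak), 623 to 1385 shared genes and a covariance of 0.698 to 0.902. The yki difference between tumor genotypes ranged from -0.75 to 0.15. The highest of these counts for weak tumor heads, between the tumor genotypes and for shared genes came without control replicate 3, when 1160 and 875 genes were called for weak tumor heads, 1414 and 1376 between the tumor genotypes, and 1385 were shared. In strong tumor against control, Yp3 ranged from -0.68 to 0.77, the latter called without control replicate 3, against -0.32 with all libraries, and 2 called genes turned sign without a call, cyc at -0.03 in both limma fits of TPM and srp at 0.07 with the length trend removed. For the named genes, 6364 of 7301 alternative values kept direction and side of the threshold, 883 lost and 32 gained a call, 18 moved and 4 reversed. The FPKM fits planned were not run because the table holds TPM, and the fold threshold gives no list result or covariance. In simulated counts edgeR recovered 31% and 34% of genes changed 2-fold, so a gene without a call may still have changed by that much. The simulation changed a far smaller share of genes than the 15.2% (weak) and 41.2% (strong) called against control, so its recovery need not carry over.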

Other observations

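The test of a shift from Rh6 to Rh5 and the tests with the length trend removed were chosen only after the results were seen.

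Several lists of cell type and organ markers were not called by camera with its preset correlation. Their counts of members stand beside 15.2% of all tested genes called in weak and 41.2% in strong tumor heads against control. Hemocyte markers were not called in weak tumor heads, where 4 of 17 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0573), nor in strong tumor heads, where 4 of 17 rose and 1 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.173), although the matrix gene Tig rose in both. Hemocyte markers were called higher in 4 of 20 settings in weak tumor heads, without control replicate 3 (0.00772) or weak tumor replicate 3 (0.0412), with RLE size factors and with the length trend removed, and over the 20 the adjusted p ranged from 0.00772 to 0.453. In strong tumor heads they were called in 2 of 20, without control replicate 3 (0.0456) and with the length trend removed, with a range of 0.0378 to 0.609. Fat body markers were not called either, as 3 of 20 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.47) in weak and 1 of 20 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.808) in strong tumor heads, with Tsf1 at 1.86 ± 0.15 and 2.83 ± 0.15 and the lipophorin gene apolpp at -1.55 ± 0.34, adjusted p = 0.00691 in strong tumor heads. In the glial list 3 of 15 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.768) in weak and 4 of 15 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.743) in strong tumor heads, with moody higher and Gat lower in both. Digestive enzyme genes, markers of gut, gave 1 of 14 rose and 8 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.239) in strong tumor heads, where the maltase gene Mal-A2 went against the rest (7.63 ± 0.54, adjusted p = 1.21e-05). Without control replicate 2 this list was called lower (adjusted p = 0.00465, with a range of 0.00465 to 0.504 over 20 settings). That fit keeps control replicate 1, in which Jon99Cii, betaTry and Jon99Ciii had 45.77, 63.63 and 28.78 CPM. In control replicates 2 and 3 they had 0.61 and 0.69, 0.19 and 2.73, and 0.09 and 0.28 CPM. The size of their falls therefore rests largely on 1 library, whereas the members Mal-A6 and Amy-p were not high in that library alone. Yolk protein genes were not called, as 0 of 3 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.239) in weak and 0 of 3 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.849) in strong tumor heads. Control replicate 3 decided this in weak tumor heads, where without it the yolk list was called higher (median 2.07, adjusted p = 2.04e-07, with a range of 2.04e-07 to 0.398 over 19 settings). Likewise the cuticle protein list, not called in weak tumor heads (adjusted p = 0.109), was called lower without it (median -1.18, adjusted p = 8.49e-08, with a range of 8.49e-08 to 0.567 over 20 settings).

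Several stress and metabolic lists were not called while single members were. Of all tested genes, 41.2% were called in strong and 15.2% in weak tumor heads against control, so called members near these shares do not set a list apart. For apoptosis genes, 6 of 14 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.183) in strong tumor heads. In the glycolysis list 8 of 23 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.232) there, led by Glut1 and Ldh. Cytochrome P450 genes moved in both directions, as 13 of 74 rose and 10 fell (14 and 11 adjusted over the list alone; camera adjusted p = 0.873) in weak and 18 of 74 rose and 19 fell (18 and 20 adjusted over the list alone; camera adjusted p = 0.99) in strong tumor heads, with Cyp313a1 at -2.97 ± 0.47, adjusted p = 0.00131. For insulin signalling and secreted wasting factors, 8 of 19 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.232), with a median of -0.04 and a mean of 0.71 in strong tumor heads. Ecdysone response and synthesis genes gave 3 of 20 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.696) there, with sad, an enzyme gene of the pathway, far above the rest. Among epithelial polarity and junction genes, 7 of 20 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.332), with the septate junction genes sinu (1.72 ± 0.21, adjusted p = 0.000268) and Gli (1.65 ± 0.17, adjusted p = 0.000111) higher and dlg1 lower. That list was called higher with the length trend removed (adjusted p = 0.0128, with a range of 0.0128 to 0.501 over 20 settings).

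A hypothesis of a shift between R8 opsins came from the contrast of Rh6 and Rh5. The share of Rh5 in the sum of Rh5 and Rh6 was 58.3 ± 3.1% in control, 98.4 ± 0.9% in weak tumor and 99.1 ± 0.1% in strong tumor heads (mean ± SD, n = 3), and the lowest of the 6 tumor libraries, 97.4%, was above the highest control, 60.3%. Yorkie activity may shift inner photoreceptors from Rh6 to Rh5, but this share restates the fall of Rh6 and the rise of Rh5 in weak tumor heads that prompted the hypothesis, so it does not test it, and the hypothesis stays open. The rise of Rh5 in weak tumor heads was 0.64 ± 0.17 with an adjusted p of 0.0335, whereas in strong tumor heads Rh5 fell (-0.62 ± 0.17, adjusted p = 0.0178), so there the share was higher because Rh6 fell by more. The rise in weak tumor heads was called in 8 of 20 alternatives, with an adjusted p from 0.00961 to 0.125, and ended without control replicate 2 (0.0871) or 3 (0.0523), strong tumor replicate 1 (0.0582), or weak tumor replicate 1 (0.11), 2 (0.125) or 3 (0.0594). A selective loss of Rh6 cells would also raise the share, and counts from whole heads do not distinguish it from a change of opsin choice.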
